A study of Rattus norvegicus with 8 samples.

How the data were processed

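Liver RNA from 8 male Goto-Kakizaki rats, an inbred strain that develops type 2 diabetes without obesity, was measured on 1-colour Affymetrix expression arrays, 4 arrays for the control diet and 4 for the diet with persimmon peel extract. Per the labels, total RNA was extracted with ISOGEN, a phenol reagent, purified on RNeasy columns and turned into biotin-labelled cRNA by the manufacturer's standard protocol. The deposited values are intensity values on a linear scale for 31099 probe sets. The submitters' processing notes name MAS5, without a version. MAS5 is the manufacturer's algorithm that gives each probe set 1 signal and can scale each array. The scaling target and the detection calls are not given in the sources used here, so the values were taken as deposited. The array medians lay between 33.2 and 39.2 signal units. The mean without the outer 2% of values at each end lay between 144 and 167, so the arrays did not share 1 such mean. The medians spanned 0.24 on the log2 scale, below the limit of 0.5 at which arrays would have been centred first. No sequencing depth exists for arrays, and the number of arrays limits the precision.

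The group of each array was taken from its label, and 8 columns of values were used with 0 columns left over. The design text gives 4 rats per diet, and the labels give 4 numbered livers per diet, so each array was treated as 1 animal. Gene names came from the platform annotation, with symbols brought up to date through a RefSeq gene table of assembly GRCr8 that was used for names only. Of 31042 probe sets other than the 57 manufacturer's control sets, 20826 had 1 gene symbol, 436 had several and were given no name, and 9780 had no symbol in that table. Of those with 1 symbol, 20758 were found in the RefSeq table by gene number. The position of each probe set along its transcript was not analysed here.

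The values were transformed to log2 with no pseudocount and no further normalization. Control probe sets were left out, as was the dimmest 50% of probe sets by mean log2 value over the 8 arrays, which left 15521 probe sets with a mean signal of at least 34.4, of which 12155 had 1 symbol and covered 9174 genes. The diets were compared with limma (version 3.58.1 in R 4.3.3), by lmFit and eBayes with an intensity trend, two-sided, as persimmon peel minus control diet, and a probe set was called at a Benjamini-Hochberg adjusted p under 0.05. Every adjusted p of a probe set in the text comes from this limma fit and every standard error (SE) is its moderated one. A called set is said to be higher or lower on the persimmon peel diet. Means and SDs of signals are on the linear scale.

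Fixed lists of genes, 37 in all, were compared with limma's camera at an inter-gene correlation of 0.01, on the brightest probe set of each gene, with Benjamini-Hochberg adjustment over the 32 lists that had at least 5 tested genes. The same lists were also tested with camera at an estimated correlation and with fry. Camera compares a list with the other tested genes, whereas fry tests the list's own genes between the diets. The median of each list was set against 10000 random lists of the same size matched on mean signal in 20 bins. A list's score on an array is the mean of its genes' log2 values after each gene is centred on its mean over the 8 arrays. Single values per array, such as ratios of control probe sets, were compared with an exact two-sided permutation test over the splits of the 8 arrays, for which the smallest possible p is 0.0286.

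The groups, the tests, the lists, the alternatives and the rule for naming genes were set before the data were examined. The rule names the 12 genes with the smallest p in each direction, the 4 members with the smallest p of each list past the threshold, a fixed set of genes of insulin signalling, glucose and lipid metabolism, of which 2 are not analysed here, and the leading 2 members by level of each list of other cell types. Genes named outside that rule are said to have been chosen after their values were seen. The alternatives were quantile normalization, median centring, a pseudocount of 16, no filter on dim probe sets, only the upper 30% by signal, no intensity trend, a robust fit, array weights, the replicate number as a block, each array left out in turn, a plain test per probe set, the unadjusted p, the mean of a gene's probe sets, and the other list tests. Alternatives chosen after seeing the data were the beta-actin middle to 3' ratio as a covariate, leaving out persimmon peel arrays 1 and 3 together, and only the brightest probe set of each gene. The fit was tested on simulated data for this comparison, made from the means and residual SDs of the 15521 probe sets, with 200 of them changed. It recovered 3 of 50 probe sets changed by 1.25-fold, 23 of 50 changed by 1.5-fold, 41 of 50 changed by 2-fold and 48 of 50 changed by 3-fold, called 8 unchanged sets, and called 0 sets when no change was simulated. The simulated errors were drawn independently for each probe set and array, so differences shared by many probe sets of an array were not covered. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.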

Results

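Hepatic gene expression was measured in male Goto-Kakizaki rats, a lean model of type 2 diabetes, aged 18 weeks. The rats had been fed for 12 weeks either AIN-93G, a purified rodent diet, or the same diet with an extract of persimmon peel. Each diet had 4 livers with 1 array each. The median signal per array was 33.2 to 39.2 units, and the 27 bacterial control sets reached at most 14.5 units on any array. Pairs of arrays correlated with r between 0.967 and 0.986 over the tested probe sets. The question was how the extract changed gene expression in the liver.

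Single genes of amino acid and fatty acid metabolism were lower in the livers of the persimmon peel diet, in arrays that also differed in a control ratio for RNA quality. That ratio, the log2 ratio of the middle to the 3' probe set of beta-actin, was -0.76 on the control and -1.06 on the persimmon peel diet without overlap. With it as a covariate, a fit added after seeing the data that separates ratio and diet poorly, 0 probe sets were called. Ppara, the nuclear receptor that drives fatty acid catabolism, had a signal of 94.3 ± 21.7 (SD, n = 4) on the control diet and 42.4 ± 9.82 (SD, n = 4) on the persimmon peel diet, a log2 fold change of -1.16 (SE 0.21, adjusted p = 0.00658). Cd36, a fatty acid transporter, went from 65.7 ± 5.81 to 35.9 ± 9.03 (SD, n = 4 each; log2 fold change -0.90, SE 0.19, adjusted p = 0.0156). On the persimmon peel diet Ppara and Cd36 both lay near 34.4, the lowest mean signal tested, so the size of their falls is uncertain. Tat, which starts tyrosine breakdown, went from 3899 ± 139 to 2721 ± 478 (SD, n = 4 each; log2 fold change -0.54, SE 0.11, adjusted p = 0.01). Bhmt, which remethylates homocysteine, changed by -0.58 (SE 0.12, adjusted p = 0.0149), and the urea cycle enzyme Otc by -0.30 (SE 0.07, adjusted p = 0.0246). No second probe set of Ppara, Cd36, Tat, Bhmt or Otc was tested. A fall of the whole transcript and weaker signal of 1 part therefore cannot be told apart for these genes. Tat, Bhmt and Otc did not pass under quantile normalization, without the intensity trend or without persimmon peel arrays 1 and 3, Bhmt and Otc did not pass with no filter, and Cd36 did not pass without those 2 arrays.

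Across the array 703 probe sets were lower and 66 were higher on the persimmon peel diet among 15521 tested, so that 91.4% of the 769 calls were lower. The calls covered 540 named genes with a lower set and 50 with a higher set. In 726 of the 769 the 4 arrays of a diet lay apart from the 4 of the other, which held for 12.9% of all tested sets against 2.86% by chance. At an unadjusted p under 0.05 there were 961 higher and 2083 lower sets, with 776 expected by chance in all. The log2 fold changes of the calls ran from -2.54 to 1.18, with medians of -0.64 for the lower and 0.55 for the higher sets, and 96 lower and 4 higher sets changed beyond 2-fold. After quantile normalization the split was 271 higher and 596 lower, or 68.7% lower. The numbers depended on single arrays: lower calls numbered 396 without control diet replicate 1, 294 without control diet replicate 4, 344 without persimmon peel diet replicate 1 and 460 without persimmon peel diet replicate 4. Higher calls numbered 12, 19 and 14 without control diet replicates 1, 3 and 4, and 13, 269, 15 and 31 without persimmon peel diet replicates 1, 2, 3 and 4.

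The genes with the smallest p among the lower sets were Rcbtb2, Tm9sf4, Mbnl2, Elovl5, Pdha1, Rdx, Ghr, Ube2h, Gnb1, Dhx36, Pak2 and Slc31a1. Elovl5, an elongase of polyunsaturated fatty acids, had 2 tested probe sets and both were lower, by -1.24 (SE 0.15, adjusted p = 0.0012) in the dimmer and -0.31 (SE 0.06, adjusted p = 0.014) in the brighter, whose signal went from 7175 ± 212 to 5800 ± 442 (SD, n = 4 each). The copper transporter gene Slc31a1 had 3 of its 4 sets lower, with log2 fold changes of -1.20, -0.74 and -0.61, and -0.17 in the brightest set (adjusted p = 0.297). For Ghr, the growth hormone receptor, the leading set changed by -1.02 (SE 0.14, adjusted p = 0.00212), and the brighter set of the same gene by -0.20 (SE 0.07, adjusted p = 0.116). Pdha1, a subunit of pyruvate dehydrogenase, changed by -1.08 in the leading set (SE 0.14, adjusted p = 0.00142) and by 0.07 in a set with more signal (SE 0.10, adjusted p = 0.756). Rcbtb2, Ube2h, Gnb1 and Dhx36 also had sets whose sign disagreed with the leading set. All 12 genes had another tested set, and in 6 of them another set was also called lower. In 11 of the 12 the brightest other set was brighter than the leading set, and the median log2 fold change was -1.14 over the leading sets and -0.16 over the brightest other sets, a gap that picking the leading sets by their p makes wider.

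**Figure D1:**
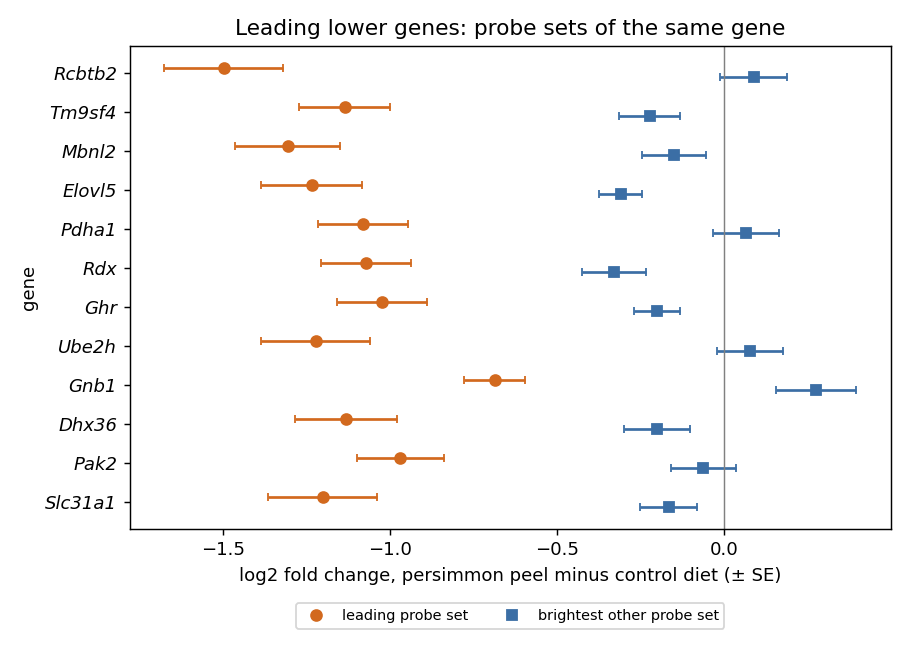
Log2 fold change (persimmon peel minus control diet, points with SE, n = 4 per diet) of the leading probe set (circles) and of the brightest other probe set (squares) of the 12 genes with the smallest p among the lower sets. The leading sets have a median of -1.14 and the brightest other sets a median of -0.16.

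The genes with the smallest p among the higher sets were Znf16l-ps1, Tmem38a, Stxbp2, Dgkd, Ssr3, Tnpo3, Med13l, Trim47, Ifi30, Snx27, Zmynd8 and Fndc10, all past the threshold. Tmem38a, an intracellular cation channel, went from 69.9 ± 24.4 to 140 ± 28.8 (SD, n = 4 each; log2 fold change 1.05, SE 0.21, adjusted p = 0.0117). Stxbp2, a regulator of vesicle fusion, changed by 0.66 (SE 0.14, adjusted p = 0.0145) and Ifi30, a lysosomal thiol reductase of antigen processing, by 0.38 (SE 0.09, adjusted p = 0.0255). Znf16l-ps1 is named as a pseudogene, so its value (0.91, SE 0.16, adjusted p = 0.00599) is uncertain. Znf16l-ps1, Tmem38a and Stxbp2 kept their call with each array left out, and the other 9 genes lost it without at least 1 array. Without persimmon peel arrays 1 and 3 together all 12 lost it. Of the 8 genes with another tested set, 0 had another set called higher, and the sets of Tmem38a, Ssr3 and Med13l disagreed in sign.

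Probe sets of the same gene changed by different amounts in more genes than these. Of 416 genes with several tested sets and at least 1 called lower, 8 had every set called lower, a number that calls missed with 4 arrays per diet keep low, and in 78.4% of the other 408 genes the mean log2 fold change of the sets not called lower was also negative. These 8, named after their values were seen, were Clint1, Elovl5, Rab6a, Rsrp1, Selenot, Serp1, Tmem106b and Tra2b. Among genes with several sets, 2.31% of the 2295 brightest sets and 13.8% of the 2981 other sets were called lower. In the difference between the dimmest and the brightest set of a gene, limma called 273 genes lower and 21 higher on the persimmon peel diet. The median of that difference per array was -1.36 ± 0.04 (SD, n = 4) on the control and -1.51 ± 0.08 (SD, n = 4) on the persimmon peel diet (exact permutation test, two-sided p = 0.0286, the smallest that this design allows). When only the brightest set of each gene was tested, a choice made after seeing the data, 78 genes were lower and 5 higher.

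Control probe sets for different parts of the same transcript also differed between the diets. The log2 ratio of the middle to the 3' set of beta-actin was -0.76 ± 0.02 (SD, n = 4) on the control diet and -1.06 ± 0.11 (SD, n = 4) on the persimmon peel diet, and all 4 arrays of each diet lay apart (exact permutation test, two-sided p = 0.0286, adjusted over 4 ratios 0.0571). The beta-actin 5' to 3' ratio was -1.68 ± 0.12 and -1.97 ± 0.22 (SD, n = 4 each; exact p = 0.0286, adjusted 0.0571). For GAPDH the 5' to 3' ratio was -0.29 ± 0.10 and -0.43 ± 0.08 (SD, n = 4 each; exact p = 0.0857), and the middle to 3' ratio was -0.58 ± 0.03 and -0.59 ± 0.05 (SD, n = 4 each; exact p = 0.857). With the beta-actin middle to 3' ratio as a covariate, added after seeing the data, limma called 0 probe sets in either direction and 543 had an unadjusted p under 0.05. The ratio itself lay apart between the diets, so that this fit separates ratio and diet poorly. Without persimmon peel arrays 1 and 3, which had the lowest ratios, 76 probe sets were lower and 1 was higher. The kept persimmon peel arrays 2 and 4 had ratios of -0.925 and -1.055, still below every control array. This fit also compared fewer arrays, so it does not separate ratio and diet either.

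**Figure D2:**
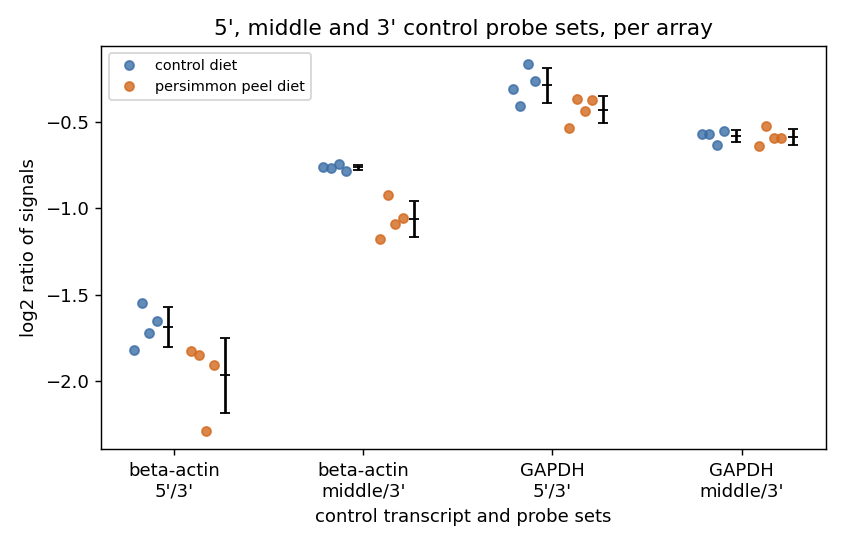
Log2 ratio of signals between control probe sets of beta-actin and GAPDH on each array (points), with the mean and SD beside each group of 4. The beta-actin middle to 3' ratio is -0.76 on average on the control diet and -1.06 on the persimmon peel diet, without overlap.

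Of the fixed gene lists, 5 were lower on the persimmon peel diet relative to the other tested genes and 0 were higher in camera's test. With an estimated correlation between genes 0 of the 5 passed (adjusted p = 0.993 for each). The bile acid synthesis and transport list had a median log2 fold change of -0.12 over 26 genes (adjusted p = 0.0341), with 2 genes lower: Slco1a1, an organic anion transporter (-0.49, SE 0.10, adjusted p = 0.0114), and the hydroxysteroid dehydrogenase gene Akr1c14 (-0.47, SE 0.13, adjusted p = 0.0497). Scp2 (-0.18) and Acox2 (-0.22) did not pass. The peroxisomal and PPARA target list had a median of -0.11 over 35 genes (adjusted p = 0.0157), with Ppara and Cd36 lower. In their brightest sets Crot (-0.43) and Phyh (-0.25) did not pass, while the dimmer set of Crot was lower (-1.10, SE 0.19, adjusted p = 0.00599). The xenobiotic metabolism list had a median of -0.08 over 55 genes (adjusted p = 0.00257) and 3 genes lower, the cytochrome P450 gene Cyp2j3 (-0.37, SE 0.09, adjusted p = 0.0279) and the sulfotransferase genes Sult1a1 (-0.24, SE 0.06, adjusted p = 0.0326) and Sult1b1 (-0.30, SE 0.08, adjusted p = 0.0407), while Cyp3a18 (-0.54, adjusted p = 0.0749) did not pass. The amino acid catabolism and urea cycle list had a median of -0.07 over 53 genes (adjusted p = 0.0157), with 5 genes lower. These were Tat, Bhmt, Otc, Glud1 (-0.29, SE 0.08, adjusted p = 0.0378) and, named after its value was seen, Got1 (-0.58, adjusted p = 0.0446). The hepatocyte marker list had a median of -0.08 over 23 genes (adjusted p = 0.00257), of which 22 had a negative log2 fold change. In their brightest sets 0 passed alone, with Tdo2 at -0.25, Apob at -0.17, Apoa2 at -0.11 and Alb at -0.11. Adjusted over the list alone, the lower genes numbered 2 for bile acids, 4 for PPARA targets, 3 for xenobiotics, 7 for amino acid catabolism and 0 for hepatocyte markers.

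The list calls were small and were lost in other tests. Besides the loss with an estimated correlation, fry's directional test gave an adjusted p of 0.838 for each, while its test of change in either direction gave adjusted p between 0.024 and 0.0872. Under quantile normalization 0 lists passed, and the medians of the hepatocyte markers (0.0043) and of amino acid catabolism (0.0074) changed sign. All 5 calls ended without the intensity trend. The bile acid call ended without control diet replicate 4 (adjusted p = 0.118), persimmon peel diet replicate 1 (0.114) or persimmon peel diet replicate 2 (0.11), the PPARA target call without persimmon peel diet replicate 1 (0.11) or 2 (0.172), and the amino acid call without control diet replicate 2 (0.0739). In the upper 30% of signal the bile acid, PPARA target and amino acid calls ended (adjusted p = 0.0644 for each), without persimmon peel arrays 1 and 3 the bile acid and PPARA target calls (0.136 for both), and with the mean of a gene's probe sets the bile acid call (0.0744). Lower lists numbered 3 without persimmon peel diet replicate 1 and 3 without persimmon peel diet replicate 2. The medians moved as well. Without persimmon peel diet replicate 2 they were -0.05 for PPARA targets, -0.05 for xenobiotics and -0.04 for amino acid catabolism, and the bile acid median was -0.06 without control diet replicate 4 or persimmon peel diet replicate 1. Without persimmon peel diet replicate 3 they were -0.17 for PPARA targets and -0.13 for xenobiotics, and without persimmon peel diet replicate 4 the PPARA target median was -0.20. Lower lists numbered 7 with no filter and 7 with the replicate block, where fatty acid oxidation (adjusted p = 0.0206 and 0.0224) and pericentral genes were added. Fatty acid oxidation also passed as lower without control diet replicate 2 or 3 or persimmon peel diet replicate 3 or 4 (adjusted p between 0.00144 and 0.0447), while its median of -0.09 went to -0.0087 without control diet replicate 4 (adjusted p = 0.178) and to -0.02 without persimmon peel diet replicate 1 (0.204) or 2 (0.284). Without control diet replicate 3 the list of antigen presentation genes passed as higher (median 0.20, adjusted p = 0.0405). Its median of 0.16 fell to 0.10 without control diet replicate 1 (adjusted p = 0.277) or persimmon peel diet replicate 3 (adjusted p = 0.291), and to 0.04 without persimmon peel arrays 1 and 3 (adjusted p = 0.37). The single genes Cyp2j3, Sult1a1, Tat, Bhmt, Otc, Glud1 and Akr1c14 kept their sign but did not pass under quantile normalization, and Cyp2j3, Sult1a1, Sult1b1 and Ifi30 did not pass with the replicate block. With each array left out in turn, Cyp2j3, Sult1a1 and Glud1 lost their call in 5 of 8 fits and Sult1b1, Otc and Akr1c14 in 6, Cd36 lost it without control diet replicate 3 or persimmon peel diet replicate 1 and Bhmt without control diet replicate 4. Ppara, with 1 tested set, passed in 17 of 18 other settings. The beta-actin ratios given above also differed between the diets, by -0.30 for the middle to 3' sets. With that ratio as a covariate, which separates ratio and diet poorly, the hepatocyte markers (-0.13, adjusted p = 0.00898) and xenobiotic metabolism (-0.18, adjusted p = 0.00896) still passed, and the PPARA target (-0.25, adjusted p = 0.101), bile acid (-0.21, adjusted p = 0.337) and amino acid (-0.13, adjusted p = 0.427) lists lost the call while their medians grew. In the same fit oxidative phosphorylation passed as lower (-0.22, adjusted p = 1.22e-06) and cholesterol synthesis as higher (0.03, adjusted p = 0.00896). Without the covariate the oxidative phosphorylation median was -0.02 (camera, adjusted p = 0.363). Both camera tests fixed the correlation between genes at 0.01. Estimated without the covariate, it was 0.64 for oxidative phosphorylation, 0.38 for hepatocyte markers, 0.32 for xenobiotic metabolism and 0.11 for cholesterol synthesis. The small p of these lists with the covariate therefore cannot be taken at face value.

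**Figure D3:**
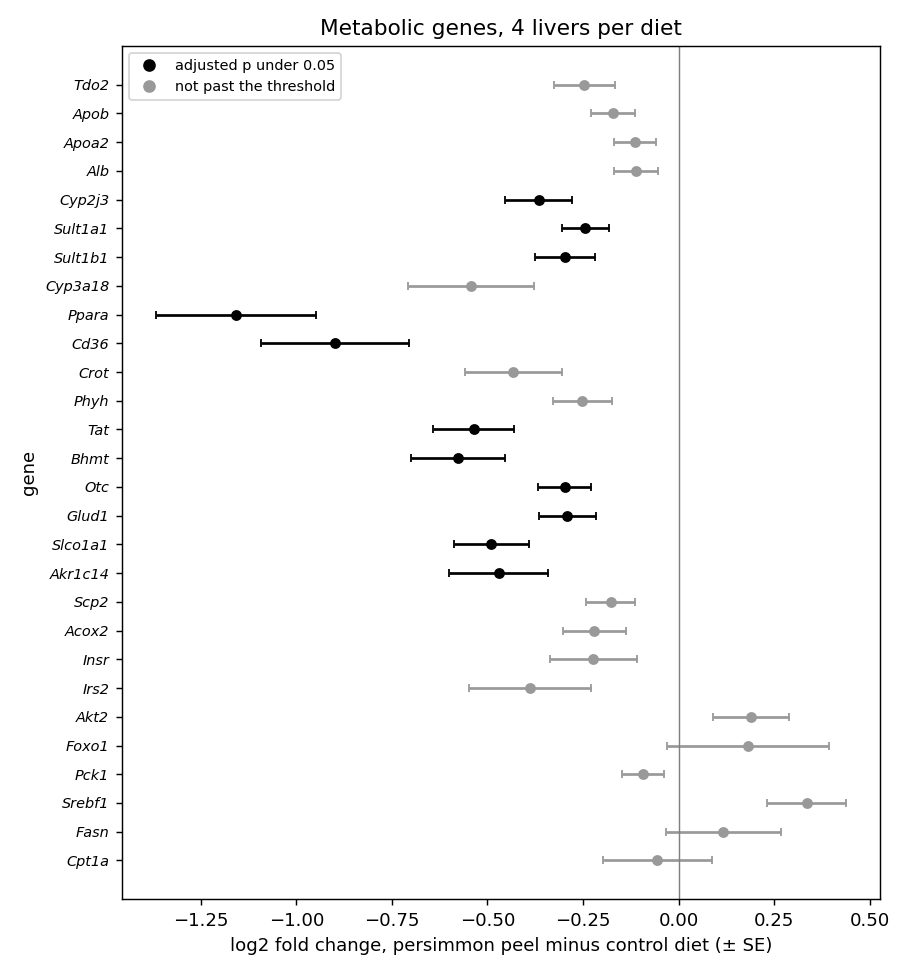
Log2 fold change (persimmon peel minus control diet, points with SE, n = 4 per diet) of the leading genes of the 5 lists past the threshold and of the fixed genes of insulin signalling, glucose and lipid metabolism. Black points passed at an adjusted p under 0.05, from Sult1a1 at -0.24 to Ppara at -1.16, and grey points did not.

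For insulin signalling, glucose and lipid metabolism, processes disturbed in type 2 diabetes, 10 of 223 tested genes were lower and 0 were higher. The same numbers passed when adjusted over these 223 genes alone. Over the whole array, the brightest set was lower in 53 and higher in 16 of 2295 genes with several sets. Among 6879 genes with 1 tested set, 124 were lower and 27 higher, so lower calls outnumbered higher ones in all genes too. Adjusted over each list alone, 2 genes were higher and 4 lower in gluconeogenesis, 1 higher and 4 lower in lipogenesis, 4 lower in fatty acid oxidation, 4 lower among PPARA targets, and 0 in insulin signalling or in glycolysis and glycogen. The 10, named in part after their values were seen, were Acadsb (-1.49, adjusted p = 0.00399), Ppara, Cd36, Tat, Got1, Me1 (-0.48, adjusted p = 0.04), Acad11 (-0.46, adjusted p = 0.03), Prkaa2 (-0.54, adjusted p = 0.0473), Elovl5 and Mpc1 (-0.28, adjusted p = 0.0295). Acadsb and Acad11 encode acyl-CoA dehydrogenases, Me1 malic enzyme, Prkaa2 a catalytic subunit of AMP-activated kinase and Mpc1 a mitochondrial pyruvate carrier subunit. By list, 1 of 62 genes of insulin signalling was lower, 3 of 33 of gluconeogenesis, 0 of 30 of glycolysis and glycogen, 2 of 38 of lipogenesis, 2 of 30 of mitochondrial fatty acid oxidation and 2 of 35 PPARA targets. The medians of those that camera did not call were 0.05 for insulin signalling (adjusted p = 0.984), -0.07 for gluconeogenesis (adjusted p = 0.305), 0.0091 for glycolysis and glycogen (adjusted p = 0.984), -0.03 for lipogenesis (adjusted p = 0.379) and -0.09 for fatty acid oxidation (adjusted p = 0.0657). The insulin signalling median was positive while camera's direction was negative.

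None of the fixed insulin signalling and lipid genes other than Ppara passed in its brightest set. Insr, the insulin receptor, was at 227 ± 18.6 on the control and 195 ± 19.96 on the persimmon peel diet (SD, n = 4 each; log2 fold change -0.22, adjusted p = 0.301), and Irs2 had a log2 fold change of -0.39 (SE 0.16, adjusted p = 0.188). Irs1 was dim, at 33.8 ± 5.64 and 32.2 ± 3.94 (SD, n = 4 each), and was not tested. Akt2 had 0.19 (adjusted p = 0.313), and its 2 other sets had -0.50 (adjusted p = 0.186) and 0.12 (adjusted p = 0.583), so its sets disagreed in sign. Foxo1 had 0.18 (adjusted p = 0.679), the gluconeogenic gene Pck1 -0.09 (adjusted p = 0.381) and Fasn 0.12 (adjusted p = 0.711). Srebf1, a transcription factor of lipogenesis, went from 1232 ± 143 to 1553 ± 180 (SD, n = 4 each; log2 fold change 0.34, SE 0.10, adjusted p = 0.0787), with the diets apart, and its other set had 0.29 (adjusted p = 0.11). Cpt1a, the entry enzyme of mitochondrial fatty acid oxidation, had -0.06 in its brighter set (SE 0.14, adjusted p = 0.869) and -1.01 in its dimmer set (SE 0.14, adjusted p = 0.00217). Over these lists 25 genes had at least 1 probe set called lower. The number of called genes in the 6 lists was 6 without control diet replicate 1, 6 without control diet replicate 4, 18 without persimmon peel diet replicate 2, 5 without persimmon peel diet replicate 1 and 6 without persimmon peel diet replicate 3.

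Markers of other cell types did not pass as lists. Medians were 0.09 for macrophages (C1qa 0.21, Clec4f 0.20), 0.05 for stellate cells and fibroblasts (Ecm1 0.36, Col3a1 -0.13), -0.04 for endothelial cells (Lyve1 -0.24, Kdr -0.10), 0.16 for lymphocytes (Rac2 0.36, Ccl5 0.33) and -0.04 for adipose tissue (Cidec -0.17, Pnpla2 -0.16), with adjusted p between 0.308 and 0.827. Fcgr2b, a receptor of sinusoidal endothelium named after its value was seen, was the 1 gene of these lists whose brightest set passed (-0.42, adjusted p = 0.009). Counting any probe set, 2 endothelial genes and 1 macrophage gene had a set called lower. Pericentral genes had a median of -0.10 and periportal genes -0.07 (adjusted p = 0.135 for both). Cholangiocyte, neutrophil, erythroid, pancreas and muscle lists had only 4, 4, 3, 1 and 1 tested genes and were not tested as lists. Their leading genes had log2 fold changes of 0.16 for Wfdc2, 0.0025 for Epcam, -0.08 for Lyz2, 0.02 for Itgb2, -0.05 for Hbb, 0.02 for Alas2, -0.28 for Cela1 and -0.03 for Myh1, none past the threshold, and Ins1 and Tnni2 were dim. The remaining lists did not pass in the main fit either. Besides the lists named above, endoplasmic reticulum stress passed with a negative median in 1 of 20 other settings (camera, adjusted p = 0.0381). Medians were 0.16 for antigen presentation (adjusted p = 0.135), 0.04 for interferon response, -0.04 for acute phase and inflammation, 0.01 for cell cycle, -0.00076 for fibrosis and matrix, 0.02 for circadian clock, 0.02 for immediate early and heat shock genes, 0.0086 for NRF2 targets, -0.03 for endoplasmic reticulum stress, -0.03 for iron metabolism, -0.02 for oxidative phosphorylation, -0.01 for cholesterol synthesis, -0.04 for lipoprotein transport, -0.06 for growth hormone response and -0.07 for retinoid and carotenoid metabolism. Median, mean and camera's direction differed in sign for acute phase, cell cycle, glycolysis and glycogen, fibrosis and matrix, NRF2 targets, insulin signalling and immediate early genes.

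**Figure D4:**
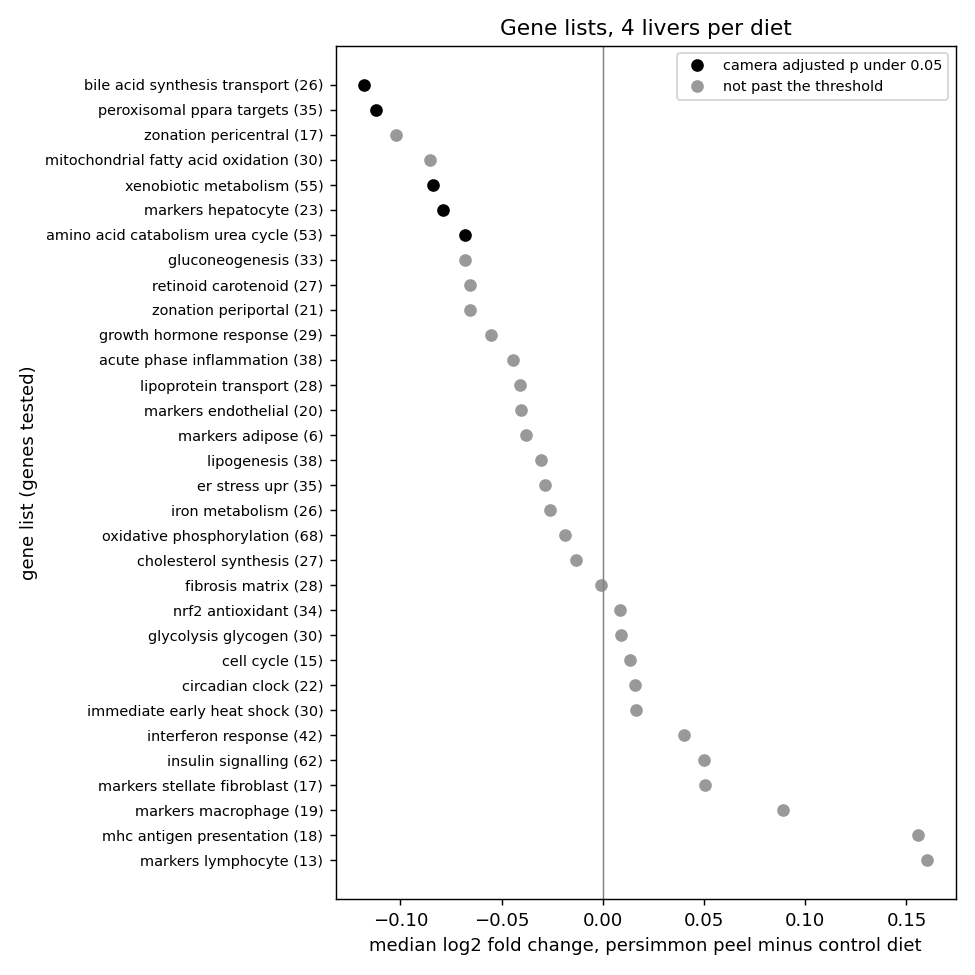
Median log2 fold change (persimmon peel minus control diet) of the 32 gene lists with at least 5 tested genes, with the number of genes in brackets. Black points are the 5 lists that passed in camera's test, with medians from -0.12 to -0.07, and grey points are the others.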

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

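The tests of splits of the arrays were set before their results were seen, and the other tests of this part were chosen after. Among 224 groups of 4 values, 13 had a value far from the other 3, where about 11.2 are expected because chance puts 1 in 20 past the limit. Single arrays stood apart in the signals of Znf16l-ps1 (50.7 in control diet replicate 1, others 37.6 to 39.3), Stxbp2 (84.6 in control diet replicate 3, others 117 to 121), Mbnl2 (272 in control diet replicate 4, others 208 to 213), Acox2 (4754 in control diet replicate 4, others 3817 to 3957), Insr (254 in control diet replicate 4, others 214 to 220), Irs1 (25.4 in control diet replicate 2, others 36.3 to 37.1), Cela1 (609 in persimmon peel diet replicate 4, others 723 to 748) and Myh1 (5330 in persimmon peel diet replicate 1, others 4816 to 4871). Single arrays also stood apart in list scores, at -0.025 for periportal genes in control diet replicate 3 (others 0.06 to 0.07), 0.16 for stellate cell and fibroblast markers in control diet replicate 4 (others -0.09 to -0.05), -0.18 for cell cycle genes in control diet replicate 3 (others 0.05 to 0.08), 0.35 for antigen presentation in persimmon peel diet replicate 3 (others -0.05 to -0.0017) and 0.42 for macrophage markers in persimmon peel diet replicate 3 (others -0.13 to -0.05).

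The first pattern is that 703 of the 769 called probe sets were lower on the persimmon peel diet. Of the 35 splits of the arrays into groups of 4, 1 gave as many calls, the real one, and the highest other split gave 5. This argues against a chance split but cannot exclude it, since 1 of 35 is the smallest share that these arrays can give. The 294 within-gene differences (1 of 35, highest other 5) and the 10 glucose and lipid genes (1 of 35, highest other 1) gave the same share. They come from the same arrays and are not separate evidence. A single scale factor per array is argued against as the whole cause, because an array's factor cancels in the difference between probe sets of a gene and 92.9% of the differences past the threshold were lower, with 329 lower and 22 higher after quantile normalization. Part of the imbalance depends on the normalization. Quantile normalization, which changes the whole distribution of each array, changed the calls to 271 higher and 596 lower, from 91.4% to 68.7% lower. Median centring, which only rescales each array, left 90 higher and 848 lower. An equal fall of whole transcripts is argued against as the usual case for genes with several sets. Lower sets were picked in 4 arrays and measured in the other 4. The median fall of the brightest other sets was 0.146 of that of the picked sets, with 0.035 to 0.284 over the 36 choices of arrays. Such medians do not speak for each gene, and 8 genes had every set called lower. A smaller fall of whole transcripts beside weaker signal of 1 part was not tested. What stays open is weaker signal away from the 3' end, through RNA integrity or labelling, for which the beta-actin middle to 3' ratio gave a difference of -0.298, although the GAPDH middle to 3' ratio differed by -0.0063, within its spread, and a diet effect on transcript ends or isoforms, which was not tested; for the 124 genes with 1 tested set that were lower, a fall of the whole transcript and weaker signal of 1 part cannot be told apart, since no second set was tested.

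The second pattern is that 5 lists of hepatocyte functions were lower. As many lists passed in 19 of the 35 splits of the arrays, up to 11 in another split, so chance cannot be excluded for the number of lists. For hepatocyte markers and amino acid catabolism, random lists matched on signal had medians as low in at least 26.4% of draws, consistent with a trend of fold change with signal level. For the xenobiotic, PPARA target and bile acid lists at most 3.37% of matched lists were as low, so signal level alone seldom gave such medians. Random lists ignore that genes of these lists vary together (estimated correlations 0.32 to 0.40), so such a trend is not excluded. The scores of these lists overlapped between the diets (exact permutation test, p between 0.229 and 0.343). A change with diet, variation between animals and a scale difference between arrays therefore cannot be told apart with 4 arrays per diet. The PPARA target score was highest on control replicate 4 (0.21) and persimmon peel replicate 3 (0.17). These arrays had the highest mean without the outer 2% of values (164 and 167). That score was lowest on persimmon peel replicates 1 and 2 (-0.24 and -0.27), as was that mean (147 and 144). The xenobiotic and bile acid scores were highest and lowest on the same arrays. Median centring left 5 lists lower and quantile normalization 0. A lower share of hepatocytes is open too, because the marker scores of the other 4 cell types did not move apart beyond their spread (smallest exact p = 0.0857 over 6 pairs), and 16 of the 23 hepatocyte markers are also in another list.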

How the results depend on the processing

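The beta-actin covariate, the fit without persimmon peel arrays 1 and 3 and the brightest set per gene were chosen after seeing the data. Of 35 named called genes, the 12 leading lower ones kept their call in every planned limma fit that tested them, while the plain test with adjustment called only 3 lower probe sets in all. Over all settings, called genes passed in the same direction in 490 of 655 values and lost the call in 164, and called lists passed in 75 of 100 and lost the call in 23. Genes not called gave 299 values close to the reported one, 16 that moved and 8 that passed, and lists not called gave 509, 17 and 11. Higher and lower probe sets numbered 271 and 596 under quantile normalization, 26 and 441 with no filter, 41 and 493 in the upper 30% of signal, 33 and 486 without the intensity trend, 0 and 3 in the plain test with adjustment, 961 and 2083 at an unadjusted p under 0.05, 5 and 78 for the brightest set per gene, 1 and 76 without persimmon peel arrays 1 and 3, and 0 and 0 with the covariate. Leaving out 1 array gave 12 to 269 higher and 294 to 942 lower sets, 5 to 18 glucose and lipid genes, 0 to 1 higher lists and 3 to 6 lower lists. The glucose and lipid genes numbered 4 with no filter, 6 in the upper 30%, 3 without the trend, 0 with the covariate and 3 without persimmon peel arrays 1 and 3. Lower lists numbered 0 under quantile normalization, 0 without the trend, 2 in the upper 30%, 0 with an estimated correlation and 0 with fry's directional test. With the covariate 3 lists were lower and 1 was higher. The 3 were hepatocyte markers, xenobiotic metabolism and, not among the 5, oxidative phosphorylation (-0.22, adjusted p = 1.22e-06 in camera). These tests used the fixed correlation of 0.01, below the estimates for these lists, so their p cannot be taken at face value. Fry's test of change in either direction, which has no direction to count, called 11 lists against 5 for camera. With the replicate block 60 probe sets were higher and 596 lower, and the numbers do not pair the animals (correlations of same-numbered deviations 0.02, -0.08, 0.05 and 0.04). Some of these settings tested fewer sets or fewer arrays, and the cause of the changes was not tested. Of the called genes and lists, those that changed sign were the medians of hepatocyte markers (0.0043) and amino acid catabolism (0.0074) under quantile normalization, and with the covariate Akr1c14 (0.13). Of those not called, 24 of 27 list medians and 7 of 17 genes changed sign in at least 1 setting, among them with the covariate Irs2 (0.48), Foxo1 (-0.66) and the cholesterol synthesis median, which passed as higher (0.032, adjusted p = 0.00896, range over its settings 0.00896 to 0.9). With the covariate the median log2 fold change of the lower calls went from -0.64 (median SE 0.14) to -0.32 (median SE 0.33), and 642 of 703 stayed negative, so the calls ended through a smaller change and a larger error. The dimmest 50% of probe sets entered only the fit with no filter, and how far background limits their signal was not tested.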

Other observations

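Genes of antigen presentation had mostly positive log2 fold changes on the persimmon peel diet, 14 of 18, with a median of 0.16, above 99.8% of lists matched on signal, but camera's adjusted p was 0.135, 0 of the genes passed alone, and with the beta-actin ratio as a covariate the median was -0.0026. RT1-CE5 had 0.45 (SE 0.17, adjusted p = 0.142) and RT1-DMb 0.37 (SE 0.17, adjusted p = 0.234), both chosen after their values were seen. The scores were 0.35 in persimmon peel diet replicate 3 and -0.05 to -0.0017 in the other 3 animals of that diet, and 19 of the 32 lists scored highest in that animal, among them macrophage markers (0.42), circadian clock (0.38), lymphocyte markers (0.38), stellate cell and fibroblast markers (0.30) and acute phase genes (0.26). Its array also had the highest median signal (39.2), so the score is not particular to antigen presentation. Ifi30, which acts in the same process, was higher on the persimmon peel diet in all 4 animals (log2 fold change 0.38, adjusted p = 0.0255), but lost its call with the replicate block and in 4 of 8 fits with 1 array left out.

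Genes of other listed processes that passed alone, chosen after their values were seen, were Crp (-0.37, adjusted p = 0.0126), an acute phase protein, Insig2 (-0.55, adjusted p = 0.0177), a regulator of sterol synthesis, Rdh16 (-0.61, adjusted p = 0.0089), a retinol dehydrogenase, Ifih1 (-0.79, adjusted p = 0.00658), a sensor of viral RNA, the chemokine gene Cxcl9 (-0.61, adjusted p = 0.0147), Hfe (-0.53, adjusted p = 0.0244) and Ireb2 (-0.61, adjusted p = 0.0183), both of iron regulation, Uqcrc2 (-0.33, adjusted p = 0.0263), a subunit of respiratory complex III, the matrix protein gene Fn1 (-0.25, adjusted p = 0.0203) and, as the only higher one, Timp3 (0.55, adjusted p = 0.0291), an inhibitor of matrix proteases.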
